A study of Homo sapiens with 4 samples.

How the data were processed

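RNA-seq was analysed from 4 libraries of human breast cancer lines, 1 per group. In MCF-7 cells, a library transiently transfected with a miR-26a mimic was compared with a control library. In MDA-MB-231 cells, a library of cells stably carrying a miR-26a sponge vector was compared with a control library. Total RNA was prepared into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. Each sample was assigned to its group from its title. The labels say that both control records duplicate earlier records, and they do not say whether a control was grown or sequenced together with its manipulated library. The title of the MCF-7 control reads miR-nc, and no protocol describes that control. The column header of the MDA-MB-231 control names a pEGFP plasmid.

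The values deposited by the authors are RPKM, a read density scaled to transcript length and library size, given per RefSeq transcript, per the file headers. The submitters' processing notes name CASAVA 1.4, Partek and genome build hg19, without saying which did what. The aligner, the annotation release, the treatment of reads that fit several places and the sharing of reads between isoforms are not given in the sources used here. RPKM divides by a number of reads per library, and which reads enter that number is not given in the sources used here, so the estimated depth below is that of this denominator. A gene's value can therefore also move when other abundant genes move. It also divides by transcript length, so isoform use can shift a summed value. The 31106 transcript rows were identical in order in all files. RPKM was summed over the rows of each gene, which gave 18221 genes, 6621 of them with more than 1 row. In 54 rows the gene symbol had been turned into a date by spreadsheet software. Those symbols were restored from the RefSeq accession.

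Counts are not part of these files, so no count test was run. Depth was estimated from the low values instead. In genes with a single transcript, RPKM times the transcript length in GENCODE 29 should be a whole number of reads at the right depth. The depth that made most values below 6.5 reads whole, within 0.05 of a read, was 13280000 reads for the MCF-7 mimic library and 14560000 for its control. It was 12840000 for the MDA-MB-231 sponge library and 16360000 for its control. Between 58.7% and 63.3% of the 1340 to 1648 values used were whole at that depth, so reads per gene are approximate. A gene with a mean of 5 to 7 RPKM had a median of 261 reads per library in MCF-7 and 270 in MDA-MB-231. Counting error alone then gives a 95% interval of about ±0.25 on the log2 ratio of 2 libraries. A gene at 1 to 1.5 RPKM had 45.4 and 51.6 reads, with intervals of ±0.63 and ±0.58. Intervals printed for single genes are exact Clopper-Pearson intervals of the approximate reads and cover counting error only. They are on the ratio of reads summed over a gene's rows and scaled to the estimated depth, without a pseudocount. In genes with more than 1 row this ratio can differ from that of the summed RPKM.

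Ratios were log2((manipulated + 1)/(control + 1)) in RPKM, a scale that understates the change of low genes. With 1 library per group no difference has a replicate check, and no p-value was computed. Genes were counted as higher or lower at 2-fold if their mean over the pair was at least 5 RPKM. For the inverse pattern between the lines, 1.5-fold and a mean of 5 RPKM in both lines were required, and each count was set beside the overlap of independent lists of the same sizes. Gene lists and sets of genes with seed sites used genes with a mean of at least 1 RPKM. The median log2 ratio of each list was given as its percentile among 10000 random lists of the same size, matched on mean expression in 10 bins. That percentile describes these libraries and is not a test of the condition. The 27 gene lists, the size rules and the rule for named genes were fixed before the data were examined. The named genes are the 10 highest and 10 lowest annotated genes per comparison with a mean of at least 5 RPKM. To these were added the 2 highest and 2 lowest members of each list described, a fixed set of genes tied to miR-26 in the literature, and the 10 genes with the largest inverse difference.

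Seed sites were searched in the longest annotated 3' UTR of each protein-coding gene in the basic set of GENCODE 29 on GRCh38. The site sequences were TACTTGAA for a miR-26 8mer, TACTTGA for a 7mer-m8 and ACTTGAA for a 7mer-A1. Genes were matched by RefSeq accession (17334 genes) or symbol (570 genes), 317 genes were not matched, and 16400 had a coding 3' UTR. The deposited files carry no coordinates, so positions come from GENCODE 29 on GRCh38 and not from the hg19 build of the submitters' notes. Sites of miR-23b, which the treatment protocol also names, were taken as a comparison set. Ranks among all 7mers used those present in at least 200 genes.

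The counts of genes were tested on simulated data drawn from the control libraries at the estimated depth, with 200 genes changed. For MCF-7, 0 of 6573 unchanged genes passed 2-fold from counting error alone, and for MDA-MB-231 0 of 6797 did. All 50 genes changed 3-fold, picked at control values above the 5 RPKM minimum, were called in the right direction in either comparison. No gene with a control value close to that minimum was changed, so recall there was not measured. Lists were tested on the observed log2 ratios, with members drawn at random and so not chosen for shared regulation. Of 200 such unshifted lists of 50 genes, 4.0% for MCF-7 and 6.5% for MDA-MB-231 fell outside the middle 95% of matched lists. Lists raised by 0.3 were called in 99.5% and 76.0% of draws. The simulation holds no variation between cultures. Alternatives tried were another pseudocount, 2 other scalings, other minimum values and folds, another handling of isoforms, and other matching and site definitions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.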

Results

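The transcriptome was measured by RNA-seq in 4 libraries, to list the genes that respond when the microRNA miR-26a is raised or blocked in breast cancer cells. MCF-7 is an estrogen-receptor-positive epithelial line, and MDA-MB-231 is a mesenchymal-like line without estrogen receptor. In MCF-7 a mimic, a synthetic RNA that acts as the mature microRNA, was transfected. In MDA-MB-231 a sponge, a vector transcript carrying binding sites that occupy the microRNA, was stably expressed. Each group had 1 library, so no value below has a replicate check. The estimated depth was 13280000 and 14560000 reads for the MCF-7 mimic and control libraries and 12840000 and 16360000 for the MDA-MB-231 sponge and control libraries. Between 10693 and 11110 genes reached 1 RPKM per library. EEF1A1, a translation elongation factor, took the most reads in all 4 libraries. Listed transcripts held between 54.9% and 60.4% of the estimated depth. Of the reads in them, the 10 most abundant genes took 6.98% in the MDA-MB-231 control and between 4.68% and 4.76% in the other libraries.

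The libraries matched their labelled lines. The 20 MCF-7 markers had a median of 52.0 RPKM with the mimic and 84.9 in the MCF-7 control, against 0.517 with the sponge and 1.46 in the MDA-MB-231 control. The 20 MDA-MB-231 markers had medians of 34.8 and 34.3 RPKM in the sponge and control libraries, against 1.63 and 0.545 in the MCF-7 mimic and control libraries. Of 10 leukocyte markers, 1 reached 1 RPKM in each library. In MCF-7 this was LCP1, an actin-bundling protein, at 43.8 RPKM with the mimic and 7.03 in the control. In MDA-MB-231 it was CD68, a lysosomal protein. Both were named after their values were seen. Mature miR-26a was not measured here, so the manipulation itself could not be checked. Of the 3 genes whose introns encode miR-26, CTDSP2 had log2 ratios of −0.95 in MCF-7 and −0.74 in MDA-MB-231, CTDSP1 −0.41 and −0.53, and CTDSPL 0.08 and −0.38.

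With the miR-26a mimic in MCF-7, the mesenchymal, matrix and interferon-response lists had medians above those of matched random lists. Reported miR-26 targets had a median below them. TGM2, a transglutaminase, was at 62.8 RPKM against 1.95 in the control, a log2 ratio of 4.44. Its counting interval was 4.77 to 5.26 on the ratio of depth-scaled reads without a pseudocount. DIO2, a thyroid hormone deiodinase, followed at 3.94, ALDH1A3, which makes retinoic acid, at 3.14, and DHRS3, a retinal reductase, at 2.95. ACTA2, smooth muscle actin, was at 3.02 and TAGLN, an actin-binding protein, at 2.65. The matrix genes TGFBI and FN1, which encodes fibronectin, were at 2.85 and 2.71. The remaining 2 of the 10 highest genes were NCRNA00284 at 2.98 and EPAS1, a hypoxia-inducible transcription factor, at 2.75. At the other end, PKP1, a desmosomal plakophilin, was at 2.08 RPKM against 31.3, a log2 ratio of −3.39. The cadherin CDH18 and CA2, a carbonic anhydrase, were both at −3.01. PGR, the progesterone receptor and an estrogen-induced gene, was at −2.04. ARHGAP36, KCNJ8, EVL, SLC24A3, NCAM2 and ANXA1 lay between −2.54 and −1.96. Of 6666 genes with a mean of at least 5 RPKM, 153 were higher and 133 lower by at least 2-fold. The median log2 ratio of these genes was −0.10, and after centring on it the counts were 188 higher and 107 lower. With a pseudocount of 0.1 they were 184 and 194, and with the most abundant isoform row 145 and 143, so which direction held more genes depended on the setting.

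Genes reported as miR-26 targets were lower as a group with the mimic. Of 50 measured members, 16 were at least 1.5-fold lower, 6 at least 1.5-fold higher and 28 neither. Their median log2 ratio was −0.38, against −0.10 for matched random lists, below all 10000 of them. The lowest members were GREB1, an estrogen-induced growth regulator, at −0.99 and CTDSP2 at −0.95. The highest were the cholesterol transporter ABCA1 at 1.79 and the cytokine IL6 at 1.44. Among the members fixed for naming, KPNA2, a nuclear import receptor, was at −0.77 and the cell cycle kinase CDK6 at −0.69. CCNE1, encoding cyclin E1, was at −0.52, SMAD1 at −0.49, MTDH at −0.44, CHD1 at −0.40 and HMGA1 at −0.39. MCL1, an anti-apoptotic protein, was at −0.33, the tumour suppressor PTEN at −0.29 and EZH2, the methyltransferase of Polycomb complex PRC2, at −0.28. The counting interval of EZH2 was −0.53 to −0.12. CCNE2, which encodes the other E cyclin, went the other way at 0.33. CCND2 and HMGA2 were below 0.1 RPKM in both MCF-7 libraries and are given no change.

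The same direction was seen in the median of all genes with a miR-26 8mer. Genes with the 8mer TACTTGAA in the 3' UTR had a median log2 ratio of −0.22 over 666 genes, below all random sets matched on expression, whose middle 95% ran from −0.14 to −0.07. Of these genes, 18.5% were at least 1.5-fold lower and 5.71% at least 1.5-fold higher. Genes with a 7mer but no 8mer had a median of −0.12 over 2097 genes, with 11.3% lower, inside the range matched on expression and below all sets matched also on 3' UTR length. Genes with no site had a median of −0.09 over 7757 genes, with 8.95% lower. Genes with an 8mer for miR-23b had a median of −0.04 over 1097 genes, above their own random range of −0.13 to −0.08, and also above it when matched on 3' UTR length and A+T share, so they are not a neutral baseline. Among 13773 7mers, TACTTGA ranked 23 from the lowest median and ACTTGAA 28. The 8mer of EZH2 lies on chromosome 7 at 148807389 to 148807396, that of KPNA2 on chromosome 17 at 68046719 to 68046726, and that of GREB1 on chromosome 2 at 11641226 to 11641233, all in the 3' UTR on GRCh38. PTEN carries 3 8mers on chromosome 10, the first at 87966733 to 87966740, and CDK6 carries 2 on chromosome 7, at 92608045 to 92608052 and 92606115 to 92606122.

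**Figure D1:**
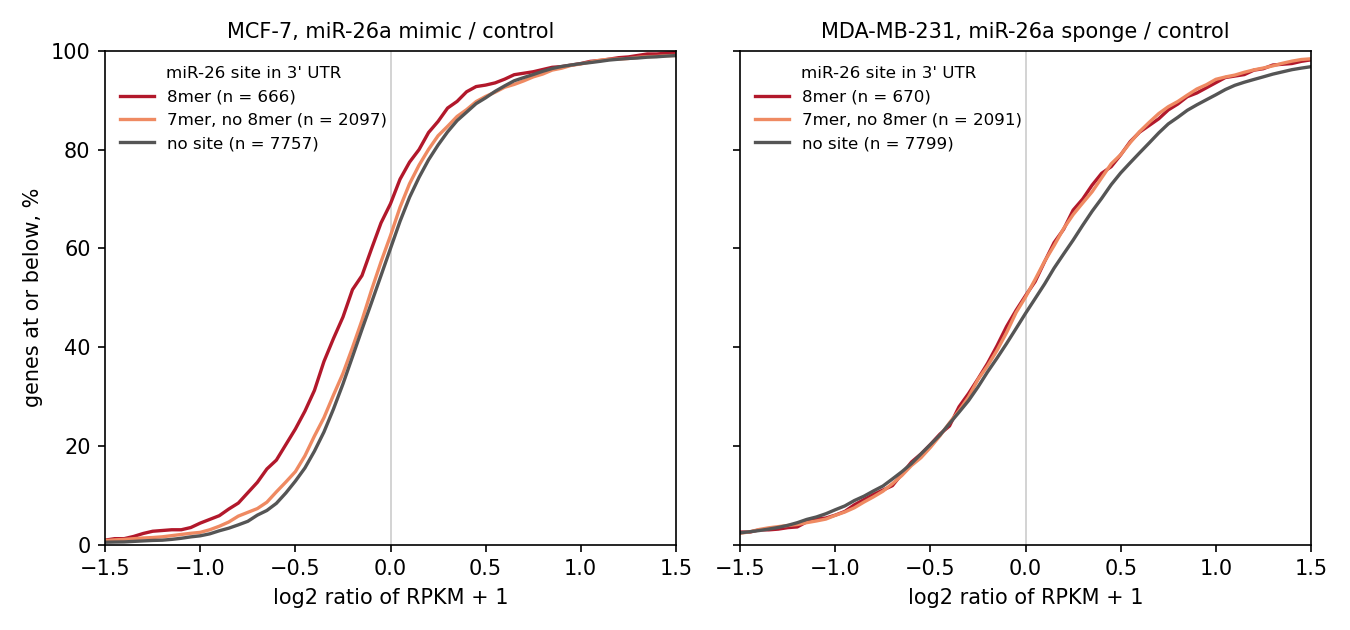
Cumulative percent of genes (y axis) at or below each log2 ratio of RPKM + 1 (x axis), for genes with a miR-26 8mer, a 7mer without an 8mer, or no site in the 3' UTR, in MCF-7 (left) and MDA-MB-231 (right). The 8mer curve lies to the left of the other 2 in MCF-7, with a median of −0.22 against −0.09 for genes without a site, while in MDA-MB-231 the curves of both site classes run together and have medians near 0.

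Most measured mesenchymal, interferon-response and NF-kB genes, and 14 of 27 matrix genes, were at least 1.5-fold higher in the mimic library. The minimum mean of 1 RPKM over the pair kept 16 of 34 mesenchymal, 27 of 53 matrix, 37 of 50 interferon and 11 of 28 NF-kB genes. A gene near 0 in the control could enter only if it was higher with the mimic, which favours higher members. Of 16 mesenchymal genes, 11 were at least 1.5-fold higher and 2 lower, with a median of 0.90. TGFBI and FN1 led this list, and CD44 at −0.89 and COL6A1 at −0.61 were its lowest. In the extracellular matrix list 2 genes were lower and the median was 0.65, or 0.38 with the most abundant isoform row. FN1 and TIMP3, at 1.74, were its highest members and LAMB2, a laminin chain, its lowest at −1.38. Of 11 integrins, 3 were higher, 1 lower and 7 neither (median 0.45), led by ITGB6 at 1.74 and ITGAV at 1.52, with ITGB4 at −0.76. Of 60 focal adhesion and actin genes, 51 stayed within 1.5-fold, 7 were higher and 2 lower (median 0.10), from TNS3 at 2.15 and TPM1 at 1.69 to EVL at −2.29. Of 37 interferon and double-stranded RNA response genes, 22 were higher and 2 lower (median 0.78), including OAS1 at 1.58 and PARP9 at 1.57, while IFITM2 was at −1.30. Of 11 NF-kB and cytokine genes, 8 were higher (median 0.89), led by IL8 at 1.70; the median was 1.38 with a pseudocount of 0.1 and 0.54 over the 3 genes left at a minimum mean of 5 RPKM. Hypoxia and glycolysis genes had a median of 0.39, TGF-beta and BMP targets 0.26, with TGFB2 at 2.03 and SMAD3 at 1.59, and p53 targets 0.19, or 0.35 with the most abundant isoform row. The medians of these 9 lists all lay above the middle 95% of matched random lists, whose own medians were near −0.10. The MDA-MB-231 marker list, which shares genes such as TGFBI and IL8 with these lists, was also above that range at 0.70 over 11 genes. At a minimum mean of 5 RPKM it turned to −0.67 over 4 genes, below the range, so its direction depends on genes with low values.

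Estrogen-response genes lay at the lower edge. Of 37 members 13 were at least 1.5-fold lower and 4 higher, with a median of −0.22 at percentile 2.38 of matched random lists. PGR and MYB, at −1.78, were the lowest members, while PRSS23 at 1.21 and AREG at 1.04 were the highest. With a pseudocount of 0.1 the percentile was 2.96, and with the most abundant isoform row 3.50, both inside the middle 95%. The MCF-7 marker list, which shares PGR, had a median of −0.35 over 20 genes, at percentile 0.15. Ribosomal protein genes had a median of −0.19 at percentile 2.13, and at 10.1 when the most abundant isoform row was used. Cell cycle genes stayed close to their control levels. The 46 G1/S and 56 G2/M genes both had a median of −0.01, inside the random range, which became 0.09 after centring. In these lists 45 and 54 genes stayed within 1.5-fold. With the most abundant isoform row, the G2/M median was 0.028 at percentile 98.3 and that of the apoptosis genes 0.062 at percentile 98.2, both above the random range. CENPE, a kinetochore motor, was the lowest G2/M gene at −0.66. The 38 apoptosis genes had a median of −0.01, which became 0.08 after centring, from TNFRSF10B at 0.94 to APAF1, the apoptosome scaffold, at −1.01. Also inside the random range were the cyclins and their kinases, near 0 and at 0.09 after centring, epithelial junctions at −0.12, PRC2 and its partners at −0.14, cholesterol synthesis at −0.13, unfolded protein genes at 0.05 and oxidative phosphorylation at −0.17.

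In MDA-MB-231 cells with the miR-26a sponge, mitotic genes were higher and stress-response genes lower than in the control. KIF20A, a mitotic kinesin, was at 54.4 RPKM against 2.72, a log2 ratio of 3.90. Its counting interval was 4.08 to 4.58 on the ratio of depth-scaled reads without a pseudocount. CDCA3 was at 3.72 and CDC20, an activator of the anaphase-promoting complex, at 3.27. MAGEC1, a cancer-testis antigen, was at 25.4 RPKM against 0.0282. KISS1, a metastasis suppressor, was at 4.21, the chemokine receptor CXCR4 at 3.48, the receptor kinase MUSK at 3.47 and LOC730755 at 3.95. SPANXB1 and SPANXA2, at 20.5 and 12.2 RPKM with the sponge, were listed at 0 in the control. They belong to a family of near-identical copies, so their values are uncertain. PAGE5 was listed at 0 with the sponge and at 29.9 RPKM in the control. GDF15, a stress-induced cytokine, was at −4.57, and MMP1, a collagenase, was at 37.1 RPKM against 761 in the control, a log2 ratio of −4.32. TRIB3, a target of the integrated stress response, was at −3.47 and HSPA5, the main chaperone of the endoplasmic reticulum, at −2.99. TCP11L2, S100P, HSPA6, RPS6KA2 and ICAM1 lay between −3.98 and −3.05.

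Of 7081 genes with a mean of at least 5 RPKM, 734 were higher and 396 lower by at least 2-fold with the sponge. The median log2 ratio of these genes was 0.14, and after centring on it the counts were 532 higher and 542 lower. With upper-quartile scaling they were 487 and 591. The excess of higher genes thus depended on the scaling. List medians are set against random lists from the same libraries, which carry the same shift.

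Of 56 G2/M genes, 55 were at least 1.5-fold higher with the sponge and 0 lower, with a median of 2.00 against 0.23 for matched random lists. CBX5, the lowest of them, was at 0.39. Of 46 G1/S genes, 37 were higher and 0 lower (median 0.84), led by RRM2 at 2.42 and GINS2 at 2.24, both needed for DNA replication. Cyclins, their kinases and inhibitors had a median of 0.70, with CCNB1 at 3.17 and CCNA2 at 2.79, while CCND2 at −2.49 and CDKN1C at −1.60 were lower. Cholesterol synthesis genes had a median of 0.73, with 18 of 28 higher, among them ACAT2 at 2.57 and DHCR24 at 2.49. Oxidative phosphorylation genes had a median of 0.71, with 25 of 36 higher. That median was 0.38 once the trend over expression, transcript length and 3' UTR A+T share was removed. These 5 medians lay above the middle 95% of matched lists.

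Of 30 unfolded protein and integrated stress response genes, 28 were at least 1.5-fold lower and 0 higher, with a median of −1.85 against 0.23 for matched lists. ATF4, which encodes the transcription factor of that response, was at −0.18 and the cystine transporter SLC7A11 at −0.44. Of 18 NF-kB and cytokine genes, 14 were lower (median −1.14), including ICAM1 at −3.05 and RELB at −2.65. Of 38 extracellular matrix genes, 19 were lower and 6 higher (median −0.60). MMP1 and LAMA5, at −2.72, were the lowest, while EFEMP1 at 2.69 and THBS1 at 2.62 were the highest. Integrins had a median of −0.64 over 12 genes, with ITGB4 at −1.88. Below the random range also lay hypoxia and glycolysis at −0.28, TGF-beta and BMP targets at −0.37, epithelial junctions at −0.28, mesenchymal genes at −0.15, estrogen-response genes at −0.40 and the MCF-7 markers at −0.76. At a minimum mean of 5 RPKM, epithelial junctions were at −0.10 and inside that range, and the MCF-7 markers turned to 0.59 over 5 genes, also inside it. Hypoxia and TGF-beta lists stayed below it with smaller medians of −0.09 and −0.22. Hypoxia genes went both ways, with VEGFA at −2.34, NDRG1 at −2.30 and PGK1 at 1.70. So did the 25 mesenchymal genes, of which 7 were at least 1.5-fold higher and 7 lower. With the trend removed as above, the mesenchymal median was −0.32, still below the range. Within the random range were apoptosis at 0.29, with BIRC5 at 2.42 and BMF at −2.43, p53 targets at −0.02, interferon genes at 0.18, focal adhesion and actin at 0.31 and ribosomal proteins at 0.22. With the trend over expression, transcript length and 3' UTR A+T share removed, the last list turned to −0.34 at percentile 0.175, below the range. Focal adhesion and actin genes were then above the range at 0.38 (percentile 99.98).

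**Figure D2:**
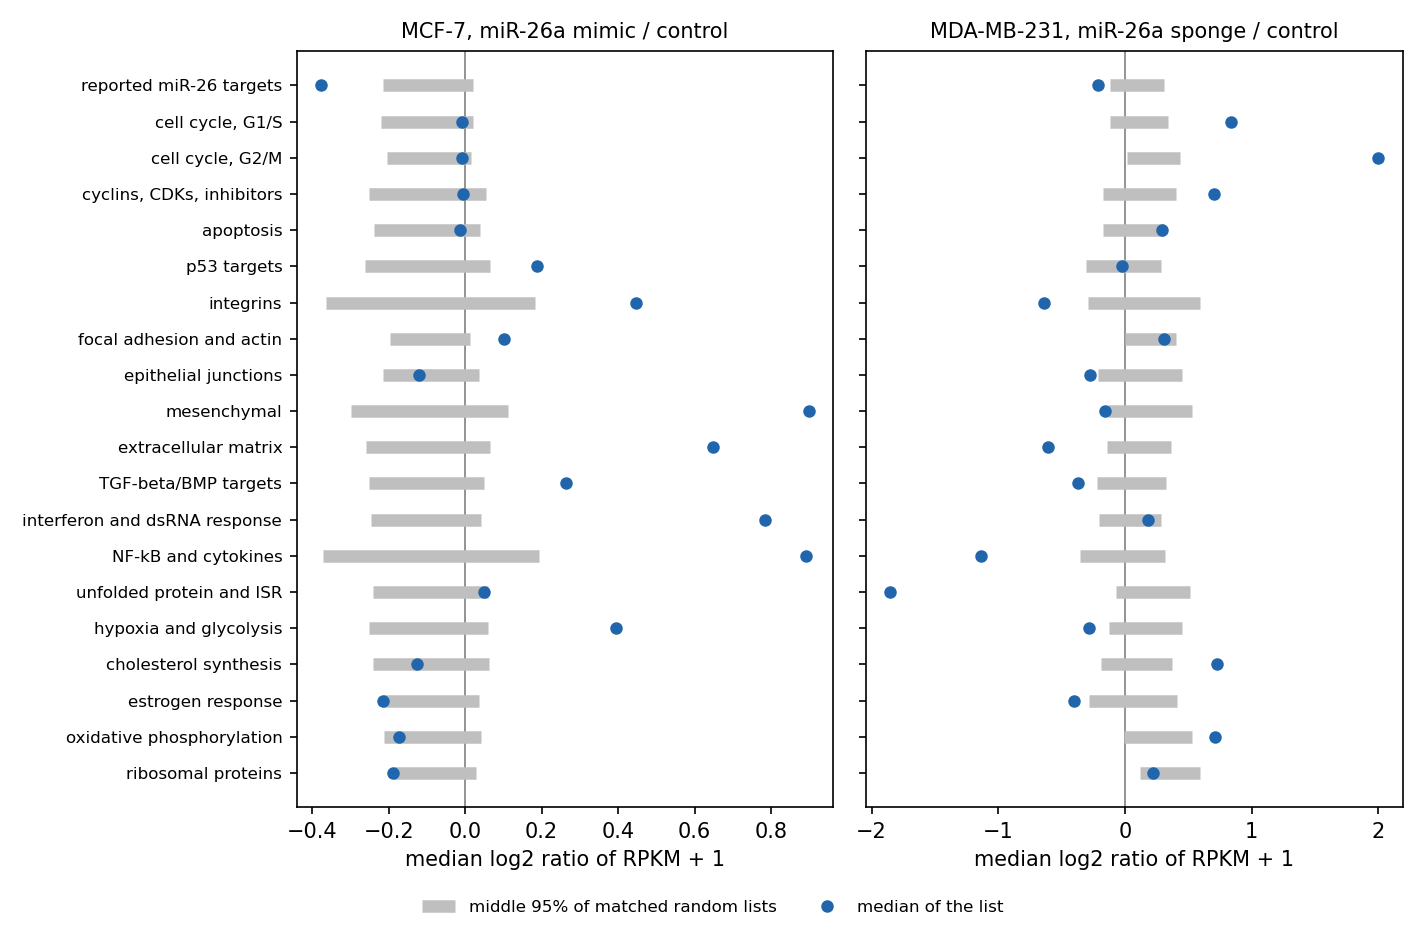
Median log2 ratio of RPKM + 1 (x axis) of each gene list (y axis) in MCF-7 (left) and MDA-MB-231 (right), as points, with grey bars for the middle 95% of medians of 10000 random lists matched on expression. The x axes differ in range. In MCF-7 the mesenchymal list lies farthest above its bar at 0.90, and in MDA-MB-231 the G2/M list at 2.00 and the unfolded protein list at −1.85 lie farthest from theirs.

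Reported miR-26 targets were not higher as a group with the sponge. Of 51 members, 10 were at least 1.5-fold higher and 11 lower, and the median of −0.21 lay below that of matched lists, at 0.09 (percentile 0.24). With the trend over expression, transcript length and 3' UTR A+T share removed, it was −0.15 at percentile 5.41, inside the range. At a minimum mean of 5 RPKM it was −0.11, still below the range. KPNA2 was at 2.03, FAM98A at 1.17, CCNE2 at 1.11, CCNE1 at 0.84, EZH2 at 0.80 and MCL1 at 0.42. CCND2 at −2.49, ABCA1 at −2.28, HMGA1 at −1.03, MTDH at −0.69, HMGA2 at −0.62, CDK6 at −0.50 and PTEN at −0.22 were lower. SMAD1 was at −0.39 and CHD1 at −0.03, with counting intervals of −1.04 to 0.04 and −0.16 to 0.09 that span 0. GREB1 was below 0.1 RPKM in both libraries. The 670 genes with an 8mer had a median of −0.01, inside the range of matched sets from −0.04 to 0.08. Of them 16.7% were at least 1.5-fold higher and 17.0% lower, against 21.2% and 17.0% of genes with no site. TACTTGA ranked 10574 from the lowest median among 13728 7mers.

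The manipulations are opposite, so a shared target would be lower with the mimic and higher with the sponge. This inverse pattern was met at 1.5-fold by 97 of the 5444 genes with a mean of at least 5 RPKM in both lines, fewer than the 111.8 of independent lists of the same sizes. The opposite pair, higher with the mimic and lower with the sponge, held 82 genes against 36.0. Both higher held 60 against 78.5 and both lower 69 against 51.3. After centring, the inverse pattern held 46 against 57.9 and the opposite pair 126 against 67.6. The inverse count exceeded that of independent lists without a minimum value, with 181 against 163.3, and at 2-fold, with 11 against 6.85. In these settings the opposite pair held 201 against 110.0 and 17 against 4.42. Both lower held 219 against 151.7 and 8 against 2.86, and both higher 115 against 118.4 and 7 against 10.6. An excess was thus not particular to the inverse pattern. The largest inverse difference was that of TXNIP, a thioredoxin inhibitor, at −1.28 with the mimic and 2.83 with the sponge. MGC16121, ZNF185, SC4MOL, KPNA2, C5orf30, UCP2, ANXA1, PHF6 and NDUFC1 followed, with differences from 3.94 to 2.53. SC4MOL, an enzyme of cholesterol synthesis, KPNA2, C5orf30 and PHF6 carry a miR-26 site. Of 94 inverse genes with a 3' UTR, 34.0% carry a site, against 25.5% of all 5326 such genes and 38.8% of the 420 that were lower in MCF-7.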

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

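Added after the data were seen were matching also on 3' UTR A+T share and the 7mer rank adjusted for 3' UTR length. In MDA-MB-231, removal of the trend over expression, transcript length and 3' UTR A+T share was also added then. No paired analysis was possible because each group has 1 library. TMM and DESeq2 size factors were not run, since they need counts. For counts, fewer or more genes entered with another minimum or fold. With a minimum mean of 1 RPKM, 275 genes were higher and 235 lower in MCF-7, 750 lower in MDA-MB-231 and 166 inverse, the last against 184.9. Without a minimum these were 289, 259, 799 and 181, the last against 163.3 for independent lists. At a minimum of 20 RPKM, MCF-7 had 50 higher and 34 lower, MDA-MB-231 362 and 123, and the inverse pattern 18 against 28.6. With 3-fold, MCF-7 had 53 and 28, MDA-MB-231 202 and 129, and with 2-fold 11 genes were inverse, against 6.85 for independent lists. Centring gave 46 inverse genes against 57.9. Upper-quartile scaling gave 57 inverse genes against 66.0, and 487 higher in MDA-MB-231, since that scaling shifts all ratios. The median of the 8mer genes in MCF-7 was −0.12 after centring, −0.26 with the shortest 3' UTR and −0.14 with all 7mer-m8 genes, below the random range each time. In MDA-MB-231 it was −0.15 after centring, −0.16 with upper-quartile scaling and 0.078 at a minimum of 5 RPKM, inside the random range each time. The median of reported targets in MDA-MB-231 was −0.36 after centring and −0.36 with upper-quartile scaling. It was −0.15 and inside the random range with the trend removed, and the cause was not tested. In MCF-7 it stayed below the random range under every alternative run for it. At a minimum of 5 RPKM, the MDA-MB-231 markers in MCF-7 reversed to −0.67 over 4 genes and the MCF-7 markers in MDA-MB-231 to 0.59 over 5 genes, since few members remained. Of the other list medians under alternatives, 247 stayed on their side of the random range and inside the 95% binomial interval of their own median, 18 left that interval, 4 entered the range and 4 left it. Those that left were G2/M and apoptosis in MCF-7 with the most abundant isoform row, and focal adhesion and ribosomal proteins in MDA-MB-231 with the trend removed, where ribosomal proteins turned to −0.34. By a score adjusted for 3' UTR length, TACTTGA ranked 1 in MCF-7 and 10630 in MDA-MB-231. That score uses means and grows with the number of genes, so it differs from the median rank by more than the length adjustment. Depth limits genes near 1 RPKM, where counting error alone spans ±0.63 in MCF-7.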

Other observations

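Some gene groups not described so far had values of their own. The 26 housekeeping genes had a median of −0.06 in MCF-7, which became 0.04 after centring, and 0.54 in MDA-MB-231, both inside the range of matched lists. HPRT1, often used as a reference gene, was at 1.48 with the sponge, and PGK1 at 1.70. The microRNA processing and effector genes had medians of −0.16 in MCF-7 and −0.02 in MDA-MB-231. At a minimum mean of 5 RPKM these medians were −0.09 and 0.20, inside the random range each time. PAN2, a deadenylase subunit, was the lowest member of this list in both lines, at −0.81 and −1.45. DICER1 was at −0.62 in MCF-7. Replication histones, which lack poly-A tails, had a median of −0.34 over 13 genes in MCF-7, inside the random range. In MDA-MB-231 it was −0.01 over 7 genes and 0.56 over 4 at a minimum mean of 5 RPKM, also inside that range. In the PRC2 list, JARID2 was at −0.59 in MCF-7, and PHF19 at 1.44 and CBX7 at −1.24 in MDA-MB-231, where its median was −0.20.

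All tests that follow were chosen after their patterns were seen, among them the removal of the trend. Only for that removal and for the shares of G2/M and of lower estrogen-response genes with a site was the prediction written before the value was seen. In MCF-7, the median of genes with a miR-26 8mer was lower, with 18.5% of the 666 genes at least 1.5-fold lower and 5.71% higher. Their median differed by −0.14 from that of random sets matched on expression, 3' UTR length and A+T share, outside the middle 95% of those sets, which argues against length and composition as the whole cause. The 7mer TACTTGA had a score of −2.74, the mean deviation from genes of like 3' UTR length times the square root of the number of genes, the lowest of 394 orderings of its bases. The lowest of the other orderings, CTTGAAT, had −1.24 and shares CTTGAA with the miR-26 sites. TACTTGA had the lowest such score of all 13773 7mers. Its rank among the orderings was thus fixed beforehand and does not test base composition. The 8mer median differed by −0.12 from that of genes with no site, with 7mer genes between, which restates the pattern and does not test its source, so action of the mimic through its seed stays an open hypothesis.

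In MDA-MB-231, unfolded protein genes were lower and G2/M genes higher with the sponge. The trend over expression, transcript length and 3' UTR A+T share took up 11.2% of the variance of the log2 ratios. Removing it left medians of −2.10 and 1.73, which argues against that fitted trend as the cause. A miR-26 site was present in 14.3% of the 56 G2/M genes (8 genes, exact 95% interval 6.38% to 26.2%), against 14.8% in random lists matched on expression and 3' UTR length. Direct release of these genes therefore cannot account for most of the list, while an indirect path through a released regulator stays open. A stressed or slowly dividing control culture, or another clone, cannot be told apart from the sponge with 1 library each, and 12 genes were under 0.1 RPKM in one MDA-MB-231 library and at 5 or more in the other, against 1 in MCF-7.

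In MCF-7 with the mimic, the mesenchymal, matrix and interferon lists lay above matched lists. Of 37 estrogen-response genes 13 were lower and 20 neither, and that list's place below the random range was lost with a pseudocount of 0.1 (median −0.22, percentile 2.96) and with the most abundant isoform row (3.50). MDA-MB-231 cells or RNA in that library are argued against by 14 genes abundant in both MDA-MB-231 libraries and near 0 in the MCF-7 control, whose median rise was 0.0566% of their MDA-MB-231 level, while the median of 43 higher members of the pattern would need 58.0%. Of the 13 lower estrogen-response genes, 61.5% have no miR-26 7mer or 8mer in the longest annotated 3' UTR. Such sites cannot account for those 8, while shorter matches and other 3' UTRs of these genes were not searched. Among the 13, 38.5% carry a site, inside the 7.69% to 53.8% of matched random lists. The exact 95% interval of that share, 13.9% to 68.4%, reaches past the upper bound, so the share was read as undecided, a reading chosen after it was seen. The share describes the list and not single genes, so direct repression of those 5 was not tested and stays open. A response to the transfected RNA that the control did not share may account for the interferon list, whose median was 0.78. It cannot be told apart from an effect of miR-26a, because the control is named miR-nc but no protocol says what RNA it received or how. For the whole pattern, any other difference between the mimic and control cultures cannot be told apart either, with 1 library each.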
